A study of Apis mellifera with 25 samples.

How the data were processed

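RNA was measured in 25 adult honey bee workers (Apis mellifera), with 1 bee per library. Per the labels' protocols, the workers came from reciprocal crosses of Africanized and European bees, lived for about 18 days in colonies without a queen, and were sorted by dissection into workers with active and with inactive ovaries. Polyadenylated RNA came from the abdomen without its gut, with fat body and ovaries attached. There were 13 libraries with inactive ovaries and 12 with active ovaries. Library titles begin with 1 of 4 numbers (875, 882, 888 and 894), called title prefixes here. The labels do not say what a prefix marks, and each holds 3 active libraries and 3 or 4 inactive ones. Replicate numbers follow the deposited order and only name a library.

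The deposited gene table holds raw read counts for 15314 gene identifiers in each library. Both deposited allele tables hold raw read counts at single-nucleotide positions, 97633 rows for active and 108059 rows for inactive ovaries, with a D count and a Q count per library. Some positions are listed once for each of several genes. The authors aligned reads with TopHat and used edgeR, per the submitters' processing notes, which name no versions. The genome build, annotation, counting tool, strand setting and the way reads were assigned to D and Q are not given in the sources used here. D was read as the version of the drone father and Q as that of the queen mother. Neither the labels nor the headers define these letters, and every paternal or maternal direction rests on that reading.

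None of the 15314 identifiers (0) matched the reference gene table used here, which lists 12398 genes of the assembly Amel_HAv3.1. Genes are therefore given by the identifiers of the files, at most 2 in each direction of a comparison, and scaffold positions are those of the files. The 19 gene lists fixed beforehand and their set tests could not be run without names. Bias towards the alleles of either lineage was not tested, because the files do not name the direction of each cross.

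Ovary status was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test) with title prefix as a covariate. Benjamini-Hochberg adjusted p under 0.05 made a call, and standard errors were the absolute log2 change divided by the square root of F. CPM (counts per 1e6 counts) were computed from the deposited counts with TMM-scaled library sizes. Named genes were those with the largest change among calls with a log2 CPM of at least 4 and the same direction in all 4 prefixes. This design, the rule for naming genes and most alternatives were fixed before the data were examined.

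Many positions had nearly equal D and Q counts in every library, as when a read is counted for both parents. D equalled Q in every library of a prefix at 25.6% to 32.4% of the positions in genes with enough reads. A position was used in a prefix when at least 2 libraries had at least 10 reads and the sum of (D − Q) squared over D + Q was not in the lower 0.01 tail of a chi-square distribution. These separating positions made up 33.6% to 41.3% of the positions judged. The rule was chosen after the spread of the values had been seen and before any gene was called. It keeps positions with unequal counts, so it favours larger ratios in either direction. Every position, and only positions above the chi-square median, were tried as alternatives.

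Counts at separating positions were summed per gene, library and parent. Genes with at least 10 reads in at least 2 libraries of each prefix were tested with the edgeR quasi-likelihood test, with a block for each library and a parental ratio for each prefix. The contrast was the mean log2 ratio of paternal to maternal counts over the 4 prefixes. The difference between ovary statuses was tested in a fit of all 25 libraries, over positions present in both tables. Named genes needed the same direction in all 4 prefixes and at least 500 reads, except for the test of the difference, where the smallest p decided. A read can be counted at several positions of a gene. Of 6629 neighbouring positions of a gene at least 1000 bases apart, 14.6% had equal counts within 1 read in every column. Summed counts therefore overstate the number of independent reads.

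Each test was tested on simulated counts made from the real libraries. The ovary-status test recovered 66% of genes changed 2-fold and 97% of those changed 4-fold, and called 8 unchanged genes in a simulation of 13157 genes, 200 of them changed. The parental test recovered 75% and 92% with active ovaries (13 unchanged genes called, 1005 genes simulated) and 70% and 96% with inactive ovaries (3 called, 944 simulated). The test of the difference recovered 58% and 81% (3 called, 851 simulated). In the simulations of parental ratios, genes include the changed ones and 100 whose direction differed between prefixes so as to cancel in the contrast. Other genes had no ratio shared by the bees of a prefix, and the choice of unequal positions was not simulated. The numbers of unchanged genes called therefore do not cover false calls from these sources. In the ovary-status simulation, genes were drawn independently, did not differ between prefixes, and changed equally in all of them. Its figures therefore do not cover effects that vary between prefixes. Alternatives covered scaling, filters, tests (limma 3.58.1, DESeq2 1.42.0), the prefix term, each prefix left out, read minimums of 5 and 20, 1 position per gene, and centring of each library. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

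Total gene counts ran from 7.54 M to 37.7 M per library (median 24.1 M; M, 1e6). Each bee is a separate animal, so p-values measure the spread between bees, and any kinship among bees of a prefix was not modelled. In the tests of parental ratios each prefix had its own ratio, so that spread was the spread within prefixes. Variation of the ratio between prefixes did not enter these p-values. A gene with an extreme ratio in a single prefix could therefore be called.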

Results

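Workers of the honey bee usually do not reproduce, but in a colony without a queen some activate their ovaries and lay unfertilised eggs. RNA from the abdomen with fat body and ovaries was counted in 12 workers with active and 13 with inactive ovaries, all from crosses between Africanized and European bees. Total gene counts had a median of 27.6 M per library (M, 1e6; range 11.5 M to 34.7 M, n = 12) with active and 24.0 M (range 7.54 M to 37.7 M, n = 13) with inactive ovaries. Between 14322 and 14988 of the 15314 genes had at least 1 count in a library. The 10 most abundant genes took 18.8% ± 4.91 (SD, n = 12) of counts with active and 23.5% ± 8.02 (SD, n = 13) with inactive ovaries.

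The first comparison asked which genes differed in expression with ovary status. Of 13157 genes tested, 1481 were higher and 1362 lower with active ovaries (edgeR quasi-likelihood test, adjusted p under 0.05), together 21.6%. The median log2 change was 0.82 among the higher genes and -0.72 among the lower ones. Large changes lay on the higher side. At least 2-fold changes were found in 528 higher and 200 lower genes, at least 4-fold changes in 95 and 1, and at least 8-fold changes in 14 and 0. Abundant genes went the other way. Among the 1488 genes at 100 CPM or more, 69 were higher and 254 lower with active ovaries. Among the 10772 genes between 1 and 100 CPM, 1377 were higher and 1064 lower. Each library held abdomen, fat body and ovaries together, so a change within a tissue cannot be told from a change in tissue proportions.

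The gene GB46084 rose with active ovaries by 4.63 on the log2 scale (SE 1.30, edgeR adjusted p = 0.0153). It stood at 818 ± 762 CPM (SD, n = 12) with active and 32.1 ± 58.5 CPM (SD, n = 13) with inactive ovaries, and all 12 active libraries lay above the inactive median. GB42182, with a position at 941919 on scaffold Group1.1, rose by 4.48 (SE 1.47, edgeR adjusted p = 0.0334). Its levels were 391 ± 483 CPM (SD, n = 12) against 44.9 ± 86.9 CPM (SD, n = 13), with 10 of 12 active libraries above the inactive median. GB53119 fell by 2.47 on the log2 scale (SE 0.67, edgeR adjusted p = 0.0113), from 2306 ± 2318 CPM (SD, n = 13) to 698 ± 902 CPM (SD, n = 12). GB53116 fell by 1.69 (SE 0.42, edgeR adjusted p = 0.00622), from 553 ± 539 CPM (SD, n = 13) to 220 ± 245 CPM (SD, n = 12). Both lie on scaffold Group4.5, GB53119 with a position at 132890 and GB53116 with positions from 126675 to 129051. The SD was as large as the mean, or nearly so, in each of these genes. None of the 4 passed the threshold when prefix 882 or prefix 888 was left out, or when tested against a fold change of 1.5. All 4 passed it without prefix 875 (largest edgeR adjusted p 0.0359) and without prefix 894 (largest 0.0271). Fewer libraries alone therefore do not account for the loss without prefix 882 or 888. In the order named, log2 changes were 3.12, 2.71, -2.58 and -1.73 without prefix 882 (edgeR adjusted p 0.178, 0.281, 0.103 and 0.0723) and 4.45, 3.24, -1.61 and -1.27 without prefix 888 (adjusted p 0.135, 0.304, 0.0844 and 0.0905). GB42182 also missed it with limma-voom (log2 change 2.997, adjusted p = 0.0782), and GB53119 (-1.72, edgeR adjusted p = 0.145) and GB53116 (-1.33, edgeR adjusted p = 0.141) without the prefix term, each in the same direction.

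The difference was carried unevenly by the 4 title prefixes. Within prefix 888, 1755 genes were higher and 1417 lower with active ovaries, and within prefix 882 the numbers were 703 and 237. Within prefixes 875 and 894 the edgeR test called 0 genes each way, with 682 and 119 genes at an unadjusted p under 0.05. A test of the difference in effect between prefixes called 22 genes. The same direction in all 4 prefixes was found for 1239 of the higher and 1102 of the lower genes, which were called with all these libraries included. Leaving out prefix 882 left 40 higher and 9 lower genes, and leaving out prefix 888 left 269 and 67. Without prefix 875 there were 2055 and 2150, and without prefix 894 there were 1467 and 1244. Fewer libraries alone therefore do not account for the losses without prefix 882 or 888. In addition, 3 inactive libraries (replicate 6 of prefix 882 and replicates 8 and 9 of prefix 888) stood apart from their prefix in allele shares, as given below with the parental reads. Without these 3, 762 genes were higher and 772 lower, and GB46084 (log2 change 3.71, edgeR adjusted p = 0.0616) and GB42182 (3.30, edgeR adjusted p = 0.168) kept large changes but did not pass the threshold with fewer libraries.

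Expression as a whole moved with ovary status along its main axis. The first principal component held 29.3% of the variance, with scores of 31.4 ± 38.3 (SD, n = 12) for active and -28.9 ± 27.3 (SD, n = 13) for inactive ovaries (two-sided permutation test, p = 0.0002). In prefix 888 the means were 78.6 and -27.4, and in prefix 882 they were 32.9 and -55.0. The gap was narrower in prefix 875 (29.0 and 3.13) and in prefix 894 (-15.0 and -27.8).

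**Figure D1:**
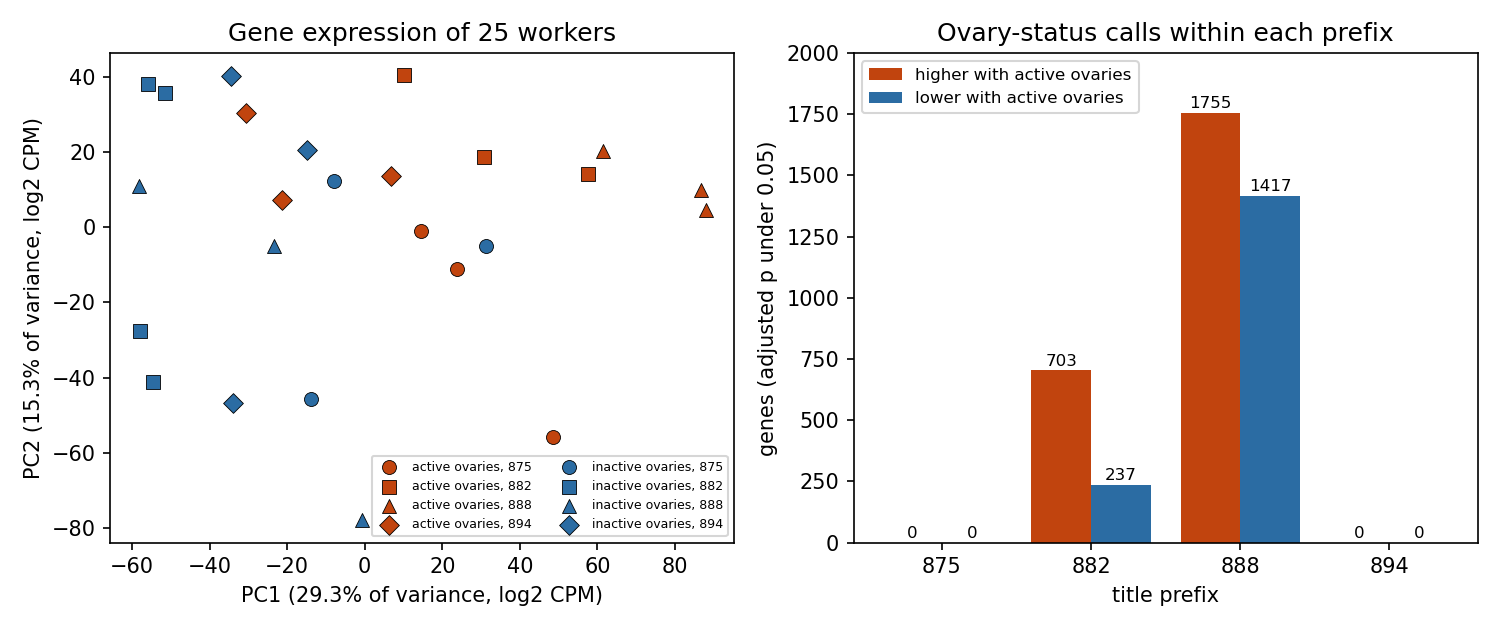
Left, scores on the first and second principal components of log2 CPM for 25 libraries, coloured by ovary status with a marker for each title prefix. Right, genes higher and lower with active ovaries (adjusted p under 0.05) within each prefix, with 1755 and 1417 in prefix 888 and 0 in prefixes 875 and 894.

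The second comparison concerned the question named in the study's title, the kinship theory of conflict within the genome, under which alleles inherited from father and mother may be expressed unequally. Paternal (D) and maternal (Q) counts were compared per gene. With active ovaries, 1005 genes were tested and 471 were called, of which 399 had more paternal and 72 more maternal reads. The paternal share of calls was 84.7% (exact Clopper-Pearson 95% interval 81.1% to 87.8%). With inactive ovaries, 944 genes were tested and 322 were called, 262 paternal and 60 maternal, a paternal share of 81.4% (interval 76.7% to 85.5%). Intervals cover counting error only, since genes are not independent. Bees of a prefix served as the replicates, so the calls describe these prefixes and do not test for a bias across prefixes in general. The split did not differ between statuses in Fisher's exact test (two-sided p = 0.244, odds ratio 1.27, 95% interval 0.854 to 1.88).

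The paternal excess reached beyond the called genes. At separating positions, which were selected for unequal counts, the median log2 ratio of tested genes was 0.33 with active and 0.25 with inactive ovaries, and 82.3% and 73.8% of tested genes had a ratio above 0. With every position that had enough reads, the median fell to 0.08 with active ovaries (2822 genes) and 0.04 with inactive ovaries (2634 genes). When each library was centred on its median gene, the calls became 247 paternal and 117 maternal with active ovaries (67.9% paternal). With inactive ovaries they became 208 and 98 (68.0%). The median fitted log2 ratio of tested genes was then still 0.16 with active and 0.11 with inactive ovaries. Calls with the same direction in all 4 prefixes numbered 258 paternal and 45 maternal with active, and 167 and 41 with inactive ovaries. Some calls rested on a single prefix, and a D share past 0.6 or under 0.4 in every prefix left 65 paternal and 24 maternal calls with active, and 58 and 25 with inactive ovaries. Over all separating positions the D share was 54.8% ± 1.89 (SD, n = 12) with active and 55.1% ± 3.32 (SD, n = 13) with inactive ovaries, above 50% in 24 of 25 libraries. Over all positions in genes it was 51.7% ± 0.621 (SD, n = 12) and 51.6% ± 1.03 (SD, n = 13).

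The most biased genes had reads of almost a single parent. With active ovaries GB43326 (scaffold GroupUn98, 23621 to 24009) had a D share of 99.9% ± 0.211 (SD, n = 12; edgeR adjusted p = 0.000263). GB41954 (Group6.30, 190702 to 190766) had 99.5% ± 0.922 (SD, n = 12; edgeR adjusted p = 2.73e-07) with active and 99.1% ± 1.70 (SD, n = 13; edgeR adjusted p = 8.33e-05) with inactive ovaries. GB49183 (Group3.14, 426385 to 471460) had 98.9% ± 2.83 (SD, n = 13; edgeR adjusted p = 0.00013) with inactive ovaries. On the maternal side, GB52653, known from a single position (GroupUn134, 12145), had a D share of 0.124% ± 0.324 (SD, n = 12; edgeR adjusted p = 1.12e-05) with active and 0.202% ± 0.730 (SD, n = 13; edgeR adjusted p = 0.000619) with inactive ovaries. GB43376 (Group2.13, 296405 to 296415) had 1.10% ± 2.07 (SD, n = 12; edgeR adjusted p = 5.13e-06) with active ovaries. GB44589 (Group5.14, 785767 to 789417) had 0.369% ± 0.728 (SD, n = 13; edgeR adjusted p = 1.75e-06) with inactive ovaries. In each of these genes every library lay on the same side of 50%. Genes were named separately for each status, so a gene given for a single status need not be biased there only. GB43326 and GB43376 were also called in the same direction with inactive ovaries (edgeR adjusted p = 6.11e-07 and 4.48e-06). Their mean D shares there were at least 0.995 and at most 0.0149 in every prefix. When positions lacking all reads of a parent in a prefix were left out, only GB43376 and GB44589 could still be tested.

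The same genes tended to be biased with active and inactive ovaries. Of 855 genes tested in both, 205 were called paternal in both, where independent lists would share 101.7. Another 49 were called maternal in both, where 4.33 would be shared. The lists are not independent, however, since separating positions were chosen per prefix from the libraries of both statuses together. Part of the overlap and of the correlations below may therefore be built in. Only 1 gene was called in opposite directions. Across genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.93 and a Spearman correlation of 0.81.

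**Figure D2:**
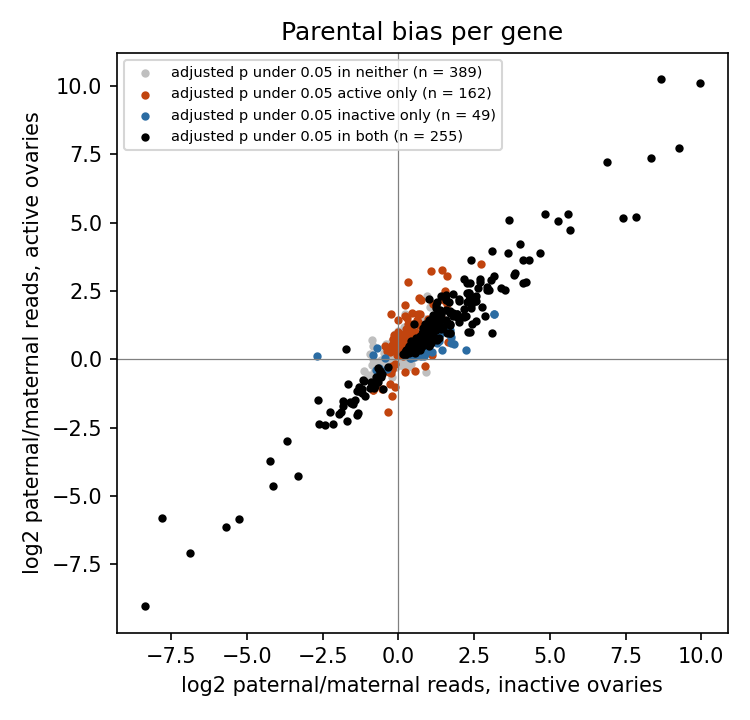
Log2 ratio of paternal to maternal reads of the 855 genes tested in both ovary statuses, inactive on the horizontal and active on the vertical axis. Each point is a gene, coloured by where it was called, with 255 genes called in both, 162 with active ovaries only and 49 with inactive ovaries only.

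The third comparison asked whether parental bias differed with ovary status. A larger share of tested genes was called with active (46.9%) than with inactive ovaries (34.1%, Fisher's exact test, two-sided p = 1.03e-08, genes not being independent). The test takes the lists as separate, though 855 genes were tested in both. These shares are over genes at separating positions. With every position, 672 of 2822 genes were called with active and 486 of 2634 with inactive ovaries. The gap in counts was not seen in a comparison chosen after the calls had been counted. Without the 3 inactive libraries described below, 288 of 859 tested genes were called. With active ovaries 271 to 338 genes were called when 3 libraries of the same prefixes were left out there too. The active side then kept fewer libraries, since prefix 882 began with 3 active and 4 inactive ones, and shares of tested genes were not compared. The direct test of the difference covered 851 genes and called 2, with 65 at an unadjusted p under 0.05. GB51879 (GroupUn93, 12187 to 51323) had a D share of 27.0% ± 10.2 (SD, n = 12) with active and 14.1% ± 4.41 (SD, n = 13) with inactive ovaries. The difference was 1.16 on the log2 scale (SE 0.21, edgeR adjusted p = 0.00929), in the same direction in 4 of 4 prefixes. Mean D shares with active and inactive ovaries were 0.204 and 0.115 in prefix 875, 0.311 and 0.124 in 882, and 0.369 and 0.139 in 888. In prefix 894, however, GB51879 had nearly equal shares (0.197 and 0.190). It missed the threshold, with differences nearly as large, without prefix 882 (0.997, edgeR adjusted p = 0.282), without prefix 888 (0.91, adjusted p = 0.114), with 1 position per gene (0.999, adjusted p = 0.358) and without the 3 libraries that stood apart (0.99, adjusted p = 0.0652). GB46096 (GroupUn149, 40632 to 53570) differed by 2.14 (SE 0.22, edgeR adjusted p = 2.77e-05), but in the same direction in only 2 of 4 prefixes. Its call rested on prefix 882, where the inactive libraries had 0 D reads of 190 at 2 separating positions (a share of up to 1.58% if reads were independent, counting error only), and the active libraries had 115 of 201. GB46096 reversed without prefix 882 and with every position, and missed the threshold with limma at a pseudocount of 2 (0.99, adjusted p = 0.127) and with positions above the chi-square median (1.88, adjusted p = 0.172). Without the 3 libraries the difference test called 9 genes, 6 more paternal and 3 more maternal with active ovaries, 1 of them shared with the 2 calls above.

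The 3 inactive libraries were told apart by lost paternal reads. A loss was counted where a gene had at least 30 reads and a D share of at most 0.05 in a library while at least 2 libraries of its prefix were balanced. Replicates 6, 8 and 9 lost paternal reads in 15, 15 and 27 genes, and no other library did so in more than 3. Maternal reads were lost in 21 to 40 genes in these 3 libraries and in 5 to 38 genes in the other 22. At separating positions the D share of inactive replicate 6 was 48.8%, the lowest of all libraries. It was 59.2% in replicate 8 and 50.1% in replicate 9, so a low D share did not mark all 3.

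**Figure D3:**
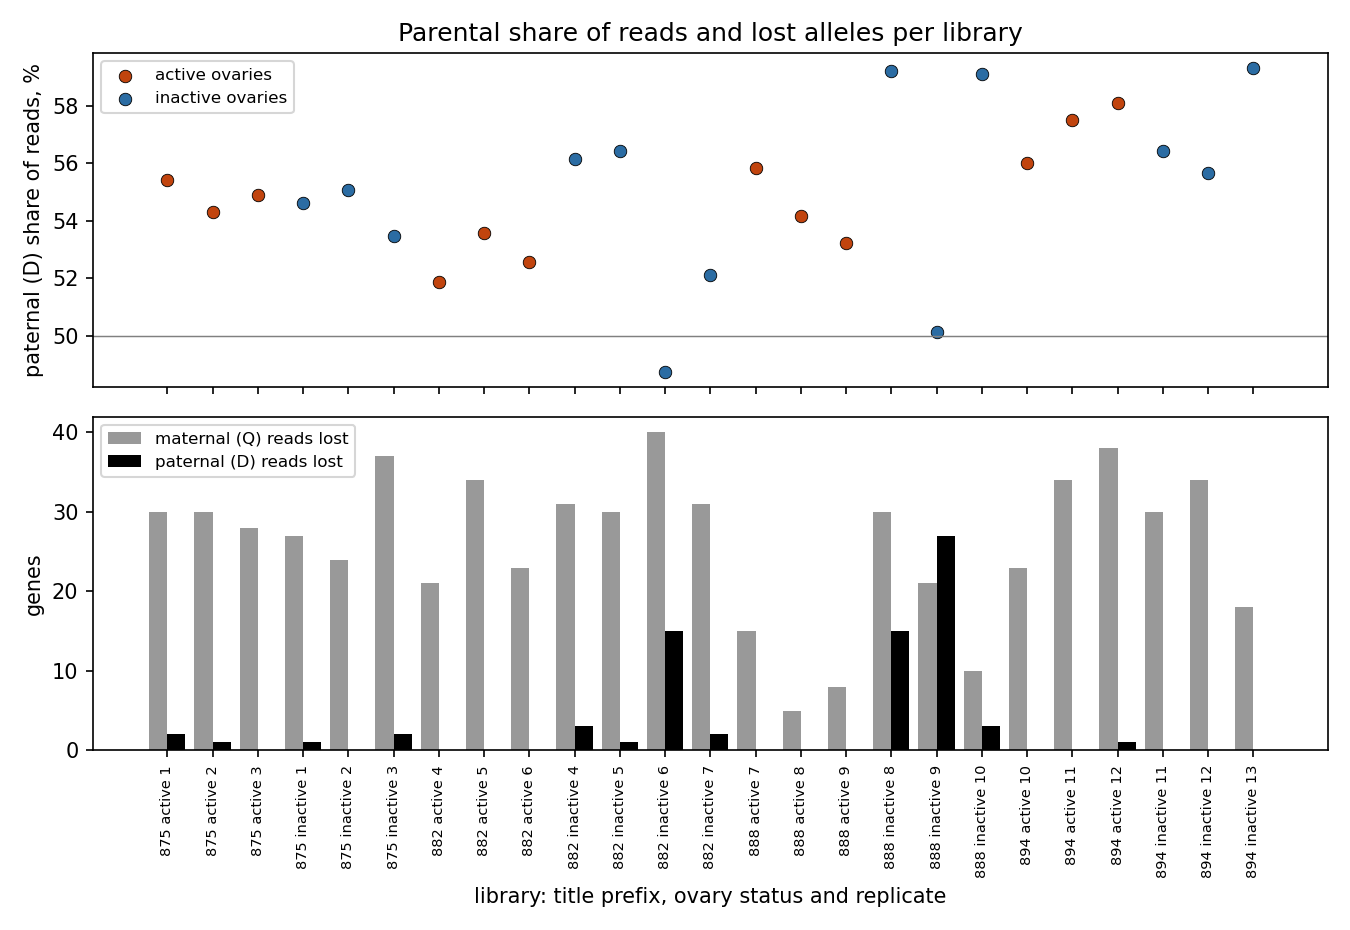
Top, D share of reads at separating positions for each library in percent, with a line at 50%. Bottom, genes in which a library lost maternal (grey) or paternal (black) reads, with 15, 15 and 27 paternal losses in inactive replicates 6, 8 and 9 and at most 3 elsewhere.

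Genes biased towards a parent were less often changed with ovary status in 3 of the 4 lists. Of maternal calls, 16.7% with active ovaries were also called for ovary status, against 28.9% of other tested genes (12 of 72 genes, Fisher's exact test, two-sided adjusted p = 0.0383). With inactive ovaries the shares were 15.0% against 29.9% for maternal calls (adjusted p = 0.0247) and 22.5% against 31.4% for paternal calls (adjusted p = 0.0247). Paternal calls with active ovaries stood at 25.8% against 29.5% (adjusted p = 0.223). Adjustment was over these 4 tests, and genes are not independent. The active and inactive lists also overlap, with 49 maternal and 205 paternal calls in both. The results for both statuses are therefore not separate findings.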

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

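The ratio of lost alleles, the use of 1 position per gene (an alternative set beforehand) to weigh the paternal lean, the D share outside genes, the ovary-status splits, the swaps of whole prefixes as a check on chance, the removal of active libraries and the tests of why 3 libraries stood apart were chosen only after results had been seen.

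The effect of ovary status on expression differed between title prefixes in 22 genes (1550 at an unadjusted p under 0.05). The ratio of paternal to maternal reads differed between prefixes in 211 genes with active and in 132 genes with inactive ovaries. Parental bias differed between active and inactive ovaries in 2 genes. At positions outside annotated genes, which no comparison used, the D share was 53.8% ± 1.99 (SD, n = 25), above 50% in 25 of 25 libraries.

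Calls leaned to the paternal side in both statuses. The tables argue against some accounts of this lean taken alone. Without genes with a lost allele, 80.7% of calls stayed paternal in the lower of both statuses. Against a bias of annotated genes only, the D share was 53.8% outside them and 51.6% over all positions in them, though both are RNA. With 1 position per gene, 75.8% of calls were paternal in the lower of both statuses. That cannot decide on reads counted at several positions, since such counting adds to D and Q alike. The 1 position was also taken from those chosen for unequal counts. What stays open is that queen alleles may be missing from the version the reads were compared with, since a queen carries a pair of alleles and a drone passes on a single one: in the 22 libraries that did not stand apart, maternal losses outnumbered paternal ones by 35.1 to 1 (561 against 16; over all 25 libraries 652 against 73, the 3 left out having been picked by their paternal losses), and more genes showed maternal losses in 4 of 4 prefixes. Parent-specific expression was not tested apart from this and also stays open.

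Fewer genes were called for parental bias with inactive than with active ovaries, and the log2 ratios of a gene spread more between bees of a prefix (median SD 0.70 against 0.55, and 0.50 for inactive ovaries without the 3 libraries). The bound set beforehand for the 3 libraries as its source was that, without them, the inactive count would come within 1.2 times of the active one; it did not, with 288 against 471 calls, a ratio of 1.64. That bound ignored that fewer libraries can give fewer calls. With 1 library of prefix 882 and 2 of prefix 888 left out of the active side too, the active count fell to between 271 and 338 over the 9 choices. That was 0.941 to 1.17 times the inactive count. The active side then kept fewer libraries than the inactive one, since prefix 882 began with 3 active and 4 inactive ones. The removal of active libraries was also added after the bound had failed, so the 3 libraries cannot be told apart from other sources here. Nor can ovary status: without the 3 libraries the difference test called 9 genes, and 4 of 50 splits within prefixes, the real one included, called as many (highest other, 9).

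Inactive replicates 6, 8 and 9 stood apart from their prefix. Low depth does not account for all 3, since 1 of them is deeper than the median library and the shallowest library, with 7.54 M (M, 1e6) counts, had 3 paternal losses. A mixture of RNA from 2 bees may leave few complete losses; the fewest in these libraries was exactly 5 times the most elsewhere, which just meets the bound against a mixture, but that bound was set with the values in sight and leaves the account open. Another father, or a wrong label, may give many paternal losses with usual maternal ones: the fewest paternal losses were 15, but replicate 6 had 40 maternal losses where other libraries had at most 38, and the high correlation of D shares between replicates 8 and 9 (0.829 across genes, at most 0.716 between any other libraries of a prefix) had no prediction set for it, so this account stays open too. No biological explanation was tested.

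Chance groupings of libraries were compared with the real ones. For ovary status, 1 of 100 splits, the real one, called as many genes (2843, highest other 27). That is the fewest that 100 splits can give, and the splits were drawn over all libraries, not within prefixes. Swapping D and Q in random sets of libraries gave as many calls in 1 of 100 draws, the real one, with active ovaries (471, highest other 50). With inactive ovaries it was also 1 of 100 (322, highest other 255, with 1 library swapped). Swaps of random sets of libraries therefore seldom gave such counts. Draws that swapped only 1 library gave 185 and 255 calls with inactive ovaries. Bees of a prefix may share alleles, however. Swapping D and Q in whole prefixes, 2 of the 4 at a time, called 120, 104 and 111 genes with active and 71, 59 and 51 with inactive ovaries. The 4 prefixes allow too few such swaps for a test. For the difference between statuses, 11 of 50 splits within prefixes gave at least the 2 genes called (highest other 4), so chance cannot be excluded.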

How the results depend on the processing

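Alternatives on separating positions, positions in 1 gene, genes with a lost allele and the 3 libraries apart were chosen after seeing the data. Of 138 counts under alternatives, 102 stayed within 1.5 times the reported one. Of 210 values of named genes, 185 kept their direction and side of the threshold, 23 kept their direction but missed it, and 2 reversed. The cause was not tested for any change below, except that fewer libraries or genes entered where some were left out. No paired analysis was possible because replicate numbers follow the deposited order and do not pair libraries. DESeq2 gave no adjusted p for GB42182, and GB43326, GB41954, GB52653 and GB49183 had too few reads in at least 1 prefix to be tested without positions lacking a parent. The lineage and gene-list alternatives were not run.

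For ovary status, the numbers of higher and lower genes moved to 40 and 9 without prefix 882, to 269 and 67 without prefix 888, to 220 and 13 against a fold change of 1.5, and to 762 and 772 without the 3 libraries. Without prefix 875, 2150 were lower. Other scalings, filters, DESeq2, voom, no prefix term and no prefix 894 gave 1434 to 1788 higher and 1191 to 1849 lower.

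For parental bias with active ovaries, centring gave 247 paternal and 117 maternal calls, and a D share past 0.6 or under 0.4 in every prefix left 65 and 24. With inactive ovaries centring gave 98 maternal calls, the share rule left 58 and 25, every position gave 414 paternal calls, and leaving out genes with a lost allele left 146 and 35. The split stayed on the paternal side in all of these.

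The difference between statuses was small and unstable, with counts more paternal then more maternal with active ovaries. These were 1 and 0 with 1 position per gene, 2 and 3 without positions lacking a parent, 2 and 1 at a minimum of 20 reads, 0 and 0 without prefix 882 (79 genes at an unadjusted p under 0.05), 1 and 0 without prefix 888, and 5 and 1 without prefix 894. The share rule gave 1 and 0, every position 12 and 12, positions above the chi-square median 1 and 3, positions in 1 gene 2 and 1, no lost alleles 1 and 1, and no 3 libraries 6 and 3. GB46096 reversed to -0.25 without prefix 882 (adjusted p = 0.825) and to -0.20 with every position (adjusted p = 0.957). Leaving out inactive replicate 6, 8 or 9 singly gave 2 or 3 genes. Depth limits these tests to genes with enough reads at separating positions, 851 for the difference.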

Other observations

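The tests on neighbouring genes were set down before their counts were known, but the one for ovary status followed the sight of GB53119 and GB53116 lying side by side.

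Genes that followed each other on a scaffold, among those with a position, tended to change together with ovary status. Among 4493 genes with a position, none sharing positions with another gene, 251 neighbouring pairs were called in the same direction, against 145 on average in 10000 shuffled orders (central 95% from 124 to 166; one-sided permutation p = 0.0001, the smallest these shuffles can give; adjusted p = 0.0003 over 3 tests). Shared regulation of neighbours may underlie this, as may reads that run from a gene into the next, which these counts do not separate. Whether the paired genes are directly adjacent was not established.

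Runs of linked genes with the same parental bias were not found with active ovaries, where 92 pairs were called for the same parent against 92.7 in shuffled orders (79 to 107; one-sided permutation p = 0.559). With inactive ovaries there were 59 pairs against 46.4 (36 to 57; one-sided permutation p = 0.0168, adjusted p = 0.0252). Whether the statuses differ in this was not tested.

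A small set of genes varied widely between bees of the same ovary status. Among 6241 genes with a mean of at least 16 CPM, 50 spanned a range of at least 100-fold over the inactive libraries and 58 over the active ones, with libraries under 3 counts set to 3 counts. Of these, 26 did so in both, where independent lists would share 0.465, and 3 of the 26 were called for ovary status. The median range of all 6241 genes was 3.60-fold with inactive and 3.21-fold with active ovaries.

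A single gene led the counts in 18 of 25 libraries. Over all 25 libraries it took 0.273% to 11.6% of counts, and it did not pass the threshold for ovary status (log2 change -0.71, SE 0.44, edgeR adjusted p = 0.245). Between prefixes, 829 genes differed in expression.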
